A study of Mus musculus with 6 samples.

How the data were processed

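RNA sequencing measured gene expression in the tibialis anterior, a fast muscle of the shin, of ICR mice at postnatal day 30. Per the labels, 3 libraries came from controls carrying the Pitx2 fl/z genotype and 3 from mutants that also carried MCKcre, a Cre recombinase driven by the muscle creatine kinase promoter. Per the labels' protocols, muscle from both legs was ground with beads, RNA was purified with a Qiagen kit, and libraries were made with a stranded mRNA kit from Kapa Biosystems.

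The deposited files hold whole-number read counts per gene, made by the authors with no normalization. Per the submitters' processing notes, the tools were CASAVA 1.8.2, TopHat2 2.1.0, HTSeq and DESeq2, and the genome build was mm10. The counting mode, the strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. Reads that the counter listed as not uniquely aligned, 15.51% to 22.95% of all reads listed, were counted for no gene. Genes with near-identical copies, such as ribosomal protein genes with pseudogenes, may therefore have lost reads. Each file ends with 5 summary lines that name no gene, which were left out of library sizes and tests and held 25.9% to 37.5% of all reads listed. No pair of libraries agreed within sampling noise: the chi-square statistic of their counts was 22 to 285 times its degrees of freedom. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries.

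Of 24421 genes, 13109 passed edgeR's filterByExpr and were tested. The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, group as the only term and Benjamini-Hochberg adjustment at 0.05. The fit used the default of the installed version. A newer bias-adjusted version of the same fit was also run, and the default was settled on after both results had been seen, because the planned test named no such option. Standard errors are the absolute log2 fold change divided by the square root of F, and 95% intervals use the t quantile on the total degrees of freedom. CPM, the counts scaled per library, were computed with the TMM-scaled library sizes, and library list means use log2 CPM with a prior count of 2.

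Gene lists for fibre types, metabolism, atrophy, stress, the clock, ribosomes and other cell types, 30 in all, were fixed in advance, and 29 had measured members. The list of mitochondrially encoded genes had 0. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 29 lists, and again with an estimated correlation and with fry. Members were also counted after adjustment over all genes and over the list alone. The genes named are Pitx2, Pitx1 and Pitx3, then up to 12 rises and 12 falls of largest size among genes past the threshold or, with none past it, the 10 of lowest p in each direction, leaving out gene models whose symbol is Gm with a number or ends in Rik. Per list, up to 4 members past the threshold or, with none, the 2 of highest mean CPM are named. This last part was applied only to the 12 lists past the camera threshold, a narrowing made after the data were seen. Genes outside this rule are said to be chosen after their values were seen.

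Other settings chosen before the data were examined were DESeq2 1.42.0 (Wald test, which gave 11298 genes an adjusted p), limma-voom, other scalings, robust empirical Bayes, no low-count filter, a CPM of at least 1 in 3 libraries, a replicate block, the mitochondrially encoded and 20 most abundant genes left out, each library left out in turn, a 1.5-fold minimum and a list threshold of 0.01. Chosen after seeing the data were offsets that remove each library's lowess trend (span 0.3) on transcript GC content and length, 1 surrogate variable from sva 3.50.0, and the bias-adjusted fit. Length, GC content and coordinates come from GENCODE vM21 on GRCm38, the build named mm10 in the notes, which matched 96.5% of the tested genes by symbol.

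On simulated counts with the means, library sizes and dispersions of these data, 200 of the 13109 genes were changed between the groups. Each gene was drawn independently, so trends that genes share in the real libraries were left out. Of the simulated genes 12953 passed the filter and were tested, and a changed gene that failed it would count as not called. The main test called 3% of those changed 1.5-fold, 28.4% of those changed 2-fold and 86.4% of those changed 4-fold, with 8 false calls. Exact tests of single values were two-sided permutation tests, whose smallest p for 3 libraries against 3 is 0.1.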

Results

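The data comprised 6 libraries of mouse tibialis anterior at postnatal day 30, 3 labelled control (Pitx2 fl/z) and 3 labelled mutant (the same genotype with MCKcre). The control libraries held 24295958, 29343935 and 25684144 reads in genes and the mutant libraries 19485160, 22828119 and 21437358. Reads that the counter listed as matching no feature made up 13.4% ± 0.721 of the control and 10.9% ± 1.02 of the mutant reads (SD, n = 3 each; exact permutation p = 0.1, the smallest this design allows). Ddx3y, a Y-linked gene, was found in all 6 libraries at 56.2 to 123 CPM, and Xist had 0 to 2 reads per library.

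Pitx2, the targeted gene, encodes a homeodomain transcription factor of muscle development and lies on chromosome 3 from 129199878 to 129219591 on the plus strand (GRCm38). The control libraries held 312, 432 and 170 Pitx2 reads, or 12.4, 13.7 and 6.8 CPM. The libraries labelled mutant held 214, 210 and 189 reads, or 11, 9.64 and 9.07 CPM. The difference was -0.15 on the log2 scale (SE 0.262, 95% interval -0.75 to 0.45, edgeR adjusted p = 0.828; exact permutation p = 0.7 on CPM). The library labelled control 3 lay below all 3 libraries labelled mutant, and without control 2 the difference turned to 0.05. Gene-level counts do not show which exons the reads came from, so the deletion could not be checked and the groups are given as labelled. The paralogs Pitx1 (log2 -0.63, SE 0.541, edgeR adjusted p = 0.629) and Pitx3 (log2 0.60, SE 0.298, edgeR adjusted p = 0.458) did not pass the test either; Pitx1 was at -0.02 without control 2 and -1.03 without control 3, and Pitx3 at 0.20 without mutant 2.

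The comparison of the libraries labelled mutant with the controls asks which muscle transcripts differ when MCKcre is present. The lowest p values belonged to Slc15a2, a proton-coupled peptide transporter, and Akr1e1, an aldo-keto reductase. Slc15a2 (chromosome 16, 36750177 to 36784962) had 4.98 ± 1.13 CPM in controls and 0.631 ± 0.132 in mutants (SD, n = 3 each), and Akr1e1 (chromosome 13, 4590750 to 4609174) had 3.69 ± 0.473 and 12.3 ± 1.23. Both missed the threshold in edgeR's quasi-likelihood test (adjusted p = 0.0703 for each) and passed in DESeq2. With edgeR, 0 of 13109 genes passed an adjusted p of 0.05. At an unadjusted p below 0.05 there were 748 genes higher and 787 lower, where chance gives 655 in all on average. Other splits of the 6 libraries into 3 and 3 gave 90 to 2334, so the excess is not beyond chance. DESeq2 called 55 genes higher and 31 lower.

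With all 6 libraries none of the 20 genes next described passed edgeR's test, and all 20 passed DESeq2's. The 10 higher genes of lowest p were Akr1e1, Per1, Slc15a5, Klhdc1, Eif4ebp1, Lrrc8a, Arrdc2, Lmod1, Mfsd4 and Epg5. Per1, a repressor of the circadian clock, had 24 ± 8.41 CPM in controls and 94.3 ± 20.4 in mutants (log2 1.97, SE 0.277, edgeR adjusted p = 0.214). Arrdc2, an alpha-arrestin, had 8.08 ± 3.77 and 41.5 ± 19.2 CPM (log2 2.36, SE 0.424). Eif4ebp1, which encodes a repressor of cap-dependent translation, had 23.7 ± 1.71 and 42.1 ± 3.11 CPM (log2 0.83, SE 0.141). Epg5, a factor in the fusion of autophagosomes with lysosomes, had 25.3 ± 5.42 and 52.2 ± 6.84 CPM. Lrrc8a, a subunit of the volume-regulated anion channel, had 23.2 ± 2.44 and 45.2 ± 7.57 CPM. The peptide transporter family member Slc15a5 had 2.54 ± 1.31 and 12.4 ± 1.55 CPM.

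Apart from 2610305D13Rik (log2 -1.94, edgeR adjusted p = 0.161) and Gm13154 (log2 -4.35, edgeR adjusted p = 0.104), gene models that the naming rule leaves out, the 10 lower genes of lowest p were Slc15a2, Tnfsf10, Cmpk2, Mybph, Luc7l3, Myct1, Gbp5, Lpar4, Mllt4 and Zfp950. Mybph, which encodes myosin-binding protein H, was the most abundant of them, at 304 ± 82.6 CPM in controls and 73.9 ± 36.2 in mutants (log2 -2.04, SE 0.388, edgeR adjusted p = 0.417). Mllt4, which encodes the junction protein afadin, had 123 ± 16.2 and 67 ± 10.4 CPM. Tnfsf10, the death ligand TRAIL, had 14.4 ± 1.34 and 6.39 ± 0.997 CPM, and the interferon-inducible genes Cmpk2 and Gbp5 had 6.67 ± 1.42 against 2.77 ± 0.303 and 5.05 ± 0.337 against 2.33 ± 0.33 CPM. Myct1, an endothelial gene, had 21.1 ± 6.72 and 7.45 ± 1.95 CPM, and the lysophosphatidic acid receptor gene Lpar4 had 6.86 ± 2.07 and 1.78 ± 0.897. Without control 2, edgeR called 16 of these 20 genes, and 195 genes higher and 138 lower in all, 56 of which DESeq2 also called with all libraries. Controls 1 and 3, the ones left, also differ from the mutants in how library values follow transcript length. Spearman's rho was -0.306 and -0.372 in them and 0.103 to 0.157 in mutants. The offsets that remove the trend were not run without control 2, so the calls made there were not told apart from it. The groups did not overlap for 16.3% of the genes tested, where chance gives 10% on average. How far this share varies over other splits of the libraries was not computed.

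**Figure D1:**
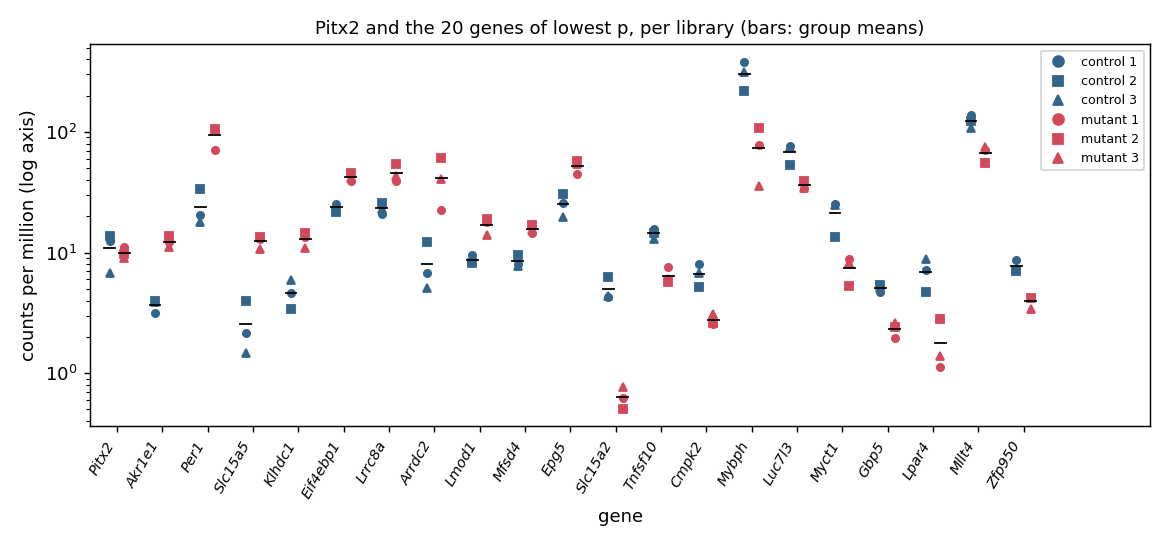
CPM (log axis) of Pitx2 and of the 20 genes of lowest p in each of the 6 libraries, with controls in blue, mutants in red, marker shape giving the replicate and black bars the group means. Slc15a2 lies at 4.3 to 6.29 CPM in controls and 0.505 to 0.768 in mutants, while the Pitx2 groups overlap.

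Of the 29 lists, 8 were higher and 4 lower in mutants by camera at the preset correlation. With an estimated correlation 0 lists passed (lowest adjusted p = 0.601). Fry passed 1, the list of neuromuscular junction and denervation-response genes (adjusted p = 0.0197). With all 6 libraries no member of any list passed edgeR's test over all genes. Without control 2, 22 members were called higher and 40 lower, under the limit on transcript length given above. Genes of ubiquitin ligases, autophagy and atrophy were higher, with 19 of 22 members higher and a median log2 of 0.51 (camera adjusted p = 5.37e-09; adjusted p = 0.601 with an estimated correlation). Adjusted over the list alone, 10 members were higher and 0 lower. The list's most abundant members were Sqstm1, an autophagy receptor, at 368 ± 58.8 CPM in controls and 501 ± 62.1 in mutants, and Trim63, which encodes the ubiquitin ligase MuRF1, at 151 ± 7.75 and 320 ± 148. Chosen after their values were seen, Foxo3, a transcription factor that drives atrophy genes, had 5.54 ± 3.11 and 14.8 ± 2.93 CPM, and Fbxo32, which encodes the ligase atrogin-1, had 115 ± 31.1 and 262 ± 148. Without mutant 2 the log2 difference went from 1.08 to 0.63 for Trim63 and from 1.19 to 0.67 for Fbxo32. The library labelled mutant 2 stood highest, 0.76 above the 6-library mean of the list, against 0.13 and 0.11 in mutants 1 and 3 and -0.41, -0.37 and -0.22 in controls.

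Of 23 glycolysis and glycogen genes 20 were higher, with a median log2 of 0.24 (camera adjusted p = 0.000606; adjusted p = 0.601 with an estimated correlation); 0 passed when adjusted over the list alone. The most abundant, Aldoa and Gapdh, differed by 0.12 (SE 0.177) and 0.04 (SE 0.181), and Gapdh turned to -0.03 with total-count scaling. Of 35 citrate cycle and fatty acid oxidation genes 28 were higher, with a median of 0.19 (camera adjusted p = 0.00329; adjusted p = 0.634 with an estimated correlation), and 0 passed when adjusted over the list alone. In that list Aco2, mitochondrial aconitase, had 1705 ± 152 CPM in controls and 2376 ± 216 in mutants, and Pdk4, an inhibitor of pyruvate oxidation, had 1027 ± 427 and 2078 ± 1800. Mutant 2 held 4096 CPM of Pdk4, and without mutant 2 the log2 difference of Pdk4 went from 1.02 to 0.06. This list no longer passed without control 2 or without mutant 2, where its median was 0.10.

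Slow-fibre contractile genes were lower in all 10 members, with a median log2 of -2.88 (camera adjusted p = 0.000886; adjusted p = 0.634 with an estimated correlation), and 5 members were lower when adjusted over the list alone. Each member except Casq2, a calsequestrin gene that was highest in control 1 at 121 CPM, was highest in the library labelled control 3. Myh7, the slow myosin heavy chain, chosen after its values were seen, had 529 CPM there, against 3.9 and 9.94 in the other controls and 9.02, 5.83 and 2.98 in mutants. Tnnt1, slow troponin T, also chosen after its values were seen, had 390 CPM in control 3 and 4.13 to 10 in the other 5 libraries. The most abundant members were Atp2a2, the slow-fibre calcium pump (217 ± 255 and 77.6 ± 4.63 CPM), and Myl3 (175 ± 238 and 46.9 ± 21.5 CPM). Without control 3 the list's median was -0.21 and it did not pass, and Atp2a2 and Myl3 turned to 0.15 and 0.30. Embryonic and cardiac-type contractile genes were lower in 7 of 8 members (median -0.70, camera adjusted p = 0.00329; adjusted p = 0.601 with an estimated correlation), with control 3 again highest, and without control 3 that list had a median of -0.09 and did not pass. Mybph alone passed when adjusted over that list, and the cardiac actin gene Actc1, its most abundant member, differed by -0.20 (SE 0.45).

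**Figure D2:**
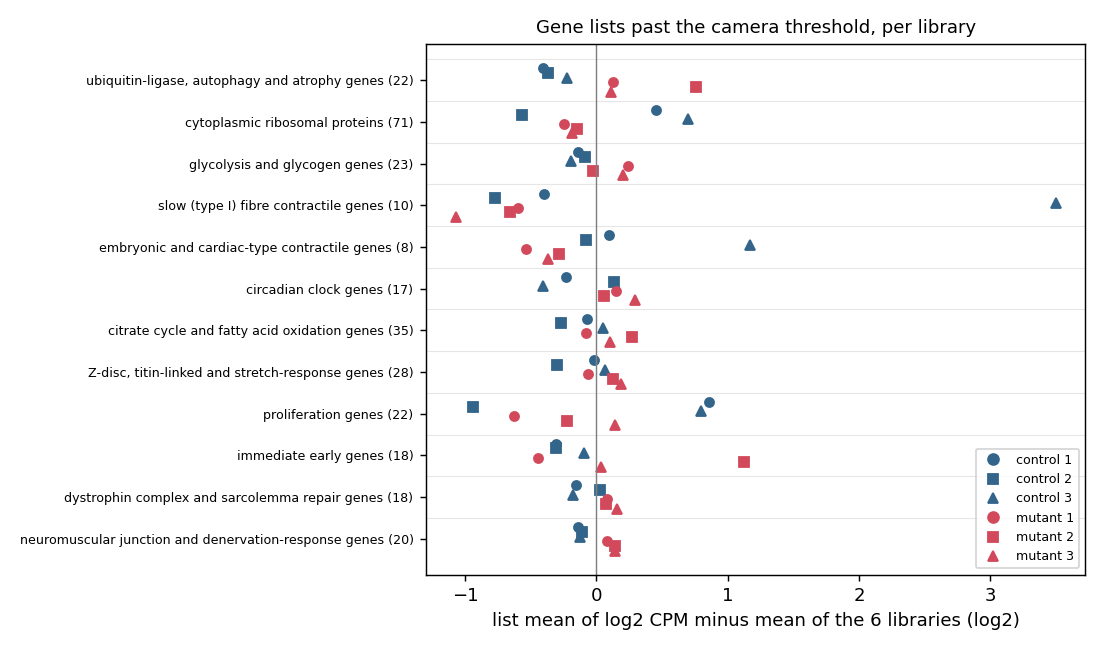
Mean log2 CPM of each of the 12 lists past the camera threshold in each library, relative to the mean of the 6 libraries, with controls in blue, mutants in red, marker shape giving the replicate and the number of measured genes in brackets. The slow-fibre list lies at 3.50 in control 3 and between -1.07 and -0.40 in the other 5 libraries, and the atrophy list is above 0 in all 3 mutants and below 0 in all 3 controls.

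Cytoplasmic ribosomal protein genes were lower in 68 of 71 members, with a median log2 of -0.48 (camera adjusted p = 5.37e-09; adjusted p = 0.684 with an estimated correlation), and 0 passed when adjusted over the list alone. Relative to the 6-library mean, controls 1 and 3 lay at 0.45 and 0.70 and control 2 at -0.57, below the mutants at -0.24, -0.15 and -0.19. The median was -0.21 without control 3 and -0.77 without control 2, where 28 members were called lower over all genes. The most abundant members, Rpl3l, a muscle ribosomal protein gene, and Rps2, differed by -0.15 (SE 0.172) and -0.06 (SE 0.188). Members with near-identical pseudogenes may have lost reads that were set aside as not uniquely aligned. Proliferation genes were lower in 19 of 22 members (median -0.75, camera adjusted p = 0.00634; adjusted p = 0.712 with an estimated correlation), with controls 1 and 3 at 0.86 and 0.79 and control 2 at -0.94. In that list, 0 members passed when adjusted over the list alone; Mki67, a marker of cycling cells, had 21.5 ± 14.3 CPM in controls and 8.7 ± 4.65 in mutants, and Pcna had 21.4 ± 5.24 and 18 ± 1.17. The proliferation list did not pass without control 1 (median -0.42), control 3 (-0.44) or mutant 2, and its median was -1.21 without control 2.

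Circadian clock genes were higher in 12 of 17 members, with a median log2 of 0.20 (camera adjusted p = 0.00329; adjusted p = 0.603 with an estimated correlation). The median was 0.07 without control 3, 0.37 without control 2 and 0.31 without mutant 2. Per1 and Per2 passed when adjusted over the list alone; Per2, chosen after its values were seen, had 3.55 ± 0.854 and 7.83 ± 2.33 CPM. The most abundant clock genes, Nr1d1 and Tef, differed by -0.24 (SE 0.283) and 0.19 (SE 0.193); without mutant 2 Nr1d1 turned to 0.04, and without control 3 Tef was at 0.03. Immediate early genes were higher in 15 of 18 members (median 0.71, camera adjusted p = 0.00634; adjusted p = 0.684 with an estimated correlation), with mutant 2 at 1.12 and the other 5 libraries between -0.45 and 0.03. Nr4a1, an orphan nuclear receptor, had 102 ± 63.5 and 346 ± 152 CPM (log2 1.77) and was called by DESeq2 (adjusted p = 0.0052) and by edgeR without control 2 (log2 2.42, adjusted p = 0.0417). In the same list Jun differed by 0.18 (SE 0.334) and turned to -0.33 without mutant 2. The immediate early list did not pass without mutant 2, where its median was -0.01, or without control 2, and 0 members passed when adjusted over the list alone.

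Z-disc, titin-linked and stretch-response genes were higher in 21 of 28 members (median 0.22, camera adjusted p = 0.00634; adjusted p = 0.601 with an estimated correlation). Tcap, the titin cap gene, passed when adjusted over the list alone and had 1038 ± 207 and 1879 ± 66.3 CPM; it was chosen after its values were seen. The giant sarcomere genes Ttn and Neb differed by 0.05 (SE 0.211) and 0.19 (SE 0.211), and Ttn turned to -0.03 with total-count scaling. Dystrophin complex and repair genes were higher in 15 of 18 members (median 0.18, camera adjusted p = 0.022; adjusted p = 0.603 with an estimated correlation), and Sntb1, which encodes a syntrophin and was chosen after its values were seen, passed when adjusted over the list alone. In that list Dag1, dystroglycan, and Trim72, a membrane repair gene, differed by 0.22 (SE 0.161) and 0.18 (SE 0.194). Neuromuscular junction and denervation-response genes were higher in 15 of 20 members (median 0.19). Camera's adjusted p was 0.0469 at the preset correlation and 0.601 with an estimated correlation, and 0 members passed when adjusted over the list alone. Hdac4, chosen after its values were seen, was the only member with an unadjusted edgeR p below 0.05 (log2 1.12, SE 0.308). The acetylcholine receptor gene Chrnb1 differed by -0.37 (SE 0.268), or -0.09 without control 1, and Ache, acetylcholinesterase, by 0.35 (SE 0.293), or 0.80 without control 2 (edgeR adjusted p = 0.0487). The Z-disc list did not pass without control 2 and had a median of 0.14 without mutant 3. The calls were also lost for the dystrophin list without control 3 or mutant 3 and for the junction list without control 3, mutant 2 or mutant 3.

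The other 17 lists did not pass in camera. The lowest adjusted p values were 0.0607 for tendon markers (lower), 0.0619 for myogenic regulators (higher), 0.0619 for endoplasmic reticulum stress genes (lower), 0.073 for macrophage and immune markers (higher), 0.132 for smooth muscle and pericyte markers and 0.136 for fibroblast and matrix genes. Redox, growth factor, excitation-contraction coupling, oxidative phosphorylation, endothelial, Schwann cell, heat shock, adipocyte, fast-fibre, red blood cell and sex-linked genes had adjusted p values of 0.321 to 0.807. For adipocyte markers the median was -0.41 while camera's direction was higher, for growth factor genes the median was -0.03 and the mean 0.16, and for the 2 measured red blood cell genes the median was 0.44 while the difference of library means was -0.07. Adjusted over the list alone, 1 endoplasmic reticulum stress gene was higher and 2 were lower, 1 adipocyte marker was higher, and 0 members passed in the other 15 lists. Tendon markers were highest in control 2, 1.51 above the mean of the other 5 libraries.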

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

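The GC and length offsets, the surrogate variable and the bias-adjusted fit were chosen after seeing the data. All 20 genes of lowest p kept their direction under each of the settings run. They were picked for low p in these same libraries and their groups did not overlap, so a kept direction was largely fixed in advance and is no support. Of them, 0 passed edgeR's test under other scalings, limma-voom, robust empirical Bayes, the stricter CPM filter, the abundant genes left out, the offsets or 1 surrogate variable. Of the 20, DESeq2 called all 20 and edgeR without control 2 called 16. In all, DESeq2 called 55 genes higher and 31 lower. With no low-count filter edgeR called 2 higher (Akr1e1, Per1) and 3 lower (Slc15a2, 2610305D13Rik, Gm13154), and with the bias-adjusted fit 2 lower (Slc15a2, Gm13154). With each library left out in turn the calls ranged from 0 to 195 higher and from 0 to 138 lower, with calls only without control 2. In that setting the groups also differ in the transcript length trend, which was not told apart from the calls. Why these settings differ was not tested. In the simulation the test found 28.4% of 2-fold changes. That share may not carry over to the real libraries, whose shared trends were not simulated.

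For lists, an estimated correlation left 0 higher and 0 lower, and fry 1 higher and 0 lower. With 1 surrogate variable 2 lists were lower, and none of the 4 lower lists of the main test was among them. With libraries left out, 6 to 10 lists were higher and 1 to 7 lower, the 1 being without control 3 and the 7 without control 2. Among the other named genes, DESeq2 called 2610305D13Rik (adjusted p = 1.81e-07), Foxo3 (0.0235), Trim63 (0.04), Per2 (0.04), Tcap (0.0052), Nr4a1 (0.0052) and Hdac4 (0.05 after rounding). Without control 2, edgeR called 2610305D13Rik (adjusted p = 0.0251), Hdac4 (0.0251), Gm13154 (0.0273), Foxo3 (0.0273), Tcap (0.0419), Nr4a1 (0.0417) and Ache (0.0487). The atrophy and glycolysis lists passed in all 17 settings run with the preset correlation. Apart from left-out libraries, the offsets ended the calls of the Z-disc, dystrophin and neuromuscular junction lists. The surrogate variable ended those of the slow-fibre, embryonic, dystrophin, circadian and ribosomal lists, limma-voom those of the proliferation and junction lists, and DESeq2 and the stricter CPM filter that of the junction list. Robust empirical Bayes and the bias-adjusted fit do not enter camera, so they gave no list result. With 1 surrogate variable the proliferation list turned higher (median 0.196, adjusted p = 0.0145) and the ribosomal list's median turned to 0.071 (adjusted p = 0.289); the cause was not tested.

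Among named genes that had not passed, these changed sign; the cause was not tested. With 1 surrogate variable the log2 values were 0.488 for Myl3, 0.155 for Actc1, -0.071 for Ttn, 0.048 for Pcna, 0.102 for Mki67, 0.054 for Rpl3l and 0.1 for Rps2. With the offsets they were -0.228 for Ttn, -0.129 for Neb and 0.081 for Rps2, and with total counts -0.032 for Ttn and -0.029 for Gapdh. With libraries left out, the ranges were -0.399 to 0.046 for Pitx2, -1.913 to 0.152 for Atp2a2, -2.44 to 0.302 for Myl3, -6.23 to 0.123 for Myl2, -0.558 to 0.203 for Actc1, -0.085 to 0.184 for Ttn, -0.009 to 0.323 for Trim72, -0.066 to 0.147 for Gapdh, -0.326 to 0.452 for Jun, -0.476 to 0.041 for Nr1d1 and -0.205 to 0.033 for Rps2. With the sign kept, they were -1.029 to -0.022 for Pitx1, 0.204 to 0.78 for Pitx3, -0.535 to -0.086 for Chrnb1, 0.127 to 0.8 for Ache, 0.027 to 0.356 for Tef, 0.077 to 0.393 for Neb, 0.142 to 0.366 for Dag1, 0.046 to 0.208 for Aldoa, -0.438 to -0.12 for Pcna and -0.277 to -0.042 for Rpl3l.

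No sign was seen that the replicate numbers pair the samples. Same-numbered libraries correlated across genes by -0.094, 0.04 and 0.087 in their deviations from the group means, and control 1 correlated best with mutant 3 (0.237). Such correlations also hold trends of whole libraries, so they cannot exclude a pairing, which the labels do not state. With the replicate block edgeR called 0 genes higher and 0 lower, as without it.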

Other observations

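Chosen after the result was seen were the tests of control 3 and of mutant 2 alone, the test of the length trend in control 3, the tests of how much trend was removed, the test of the Rn45s share, the gene-count splits, the length and GC offsets used in several tests, and the added lists of interferon-stimulated and glucocorticoid-response genes; the thresholds for the added lists were set before their values were computed. Cmpk2, Gbp5 and Tnfsf10, all known to respond to interferon, were among the lower genes of lowest p. A list of other interferon-stimulated genes was lower in 29 of 31 measured members, with all 3 controls at 0.21 to 0.39 and the mutants at -0.44, -0.34 and -0.07 around the 6-library mean. The difference of library means was -0.57 (SE 0.122, n = 3 each; exact permutation p = 0.1, the smallest possible), and -0.53 (SE 0.118) after removal of the length and GC trends. No member passed edgeR's test over all genes; camera's unadjusted p was 4.57e-11 at the preset correlation and 0.0363 with an estimated correlation. Examples chosen after their values were seen were Irf7, a regulator of interferon genes (5.73 ± 0.561 CPM in controls and 3.62 ± 0.897 in mutants), Oas2 (3.07 ± 0.341 and 1.66 ± 0.479) and Usp18 (1.96 ± 0.236 and 1.01 ± 0.244). A hypothesis is that interferon-stimulated expression may be lower in the libraries labelled mutant, and the difference of -0.571 met the bound set for it. The list was named because 3 genes of its kind had been seen lower in these same libraries, so meeting the bound is not independent support.

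The slow-fibre list was lower in the libraries labelled mutant with a difference of library means of -1.548 (SE 1.373). Without control 3 the difference was -0.187 (SE 0.237), so the pattern rests on that library. Control 3 lay 4.195 above the mean of the other 5 libraries and still 4.074 above it after removal of its length and GC trend, which argues against that trend as the source of its excess. The group difference was -1.509 (SE 1.332) after the removal, and the trend removed differed between the groups by only -0.039 (SE 0.07), far less than -1.548, which argues against it there too. A candidate explanation is slow-fibre tissue from a neighbouring muscle in control 3; the files hold no sample of such a muscle to test it.

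The ribosomal protein list was lower in the libraries labelled mutant, by a difference of -0.386 (SE 0.388). Library deviations followed transcript length across genes, with Spearman's rho of -0.306, 0.343 and -0.372 in controls and 0.103, 0.157 and 0.15 in mutants, and ribosomal transcripts are short (median 1094 bases against 3463 for all genes). After removal of the length and GC trends the difference was -0.224 (SE 0.239), and the trend removed differed by -0.162 (SE 0.151), so the trend and the genotype cannot be told apart, since the spreads are about as large as the values. Leaving out the mitochondrially encoded and the 20 most abundant genes gave -0.388, a setting that moved nothing and decides nothing. Rn45s held 2.68% ± 3.58 of control and 3.34% ± 3.56 of mutant reads. Scaling by it would shift the groups by only -0.01 (SE 0.044). That argues against carry-over of this RNA acting through library size, while other effects of carry-over were not tested. An effect of the genotype stays open and untested.

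The atrophy list was higher in the libraries labelled mutant by 0.664 (SE 0.221). Without mutant 2, the library with most immediate early expression, the difference was 0.45 (SE 0.056), and after removal of the length and GC trends 0.688 (SE 0.224), the trend removed differing by -0.024 (SE 0.016), which argues against either as the whole source. A different time of day at collection stays open: clock output and repressor genes minus activators differed by 0.585 (SE 0.445). The 10 output and repressor genes included Per1 (log2 1.97), already seen among the genes of lowest p. Their abundant members Nr1d1 and Tef differed by -0.24 and 0.19. A glucocorticoid or fasting signal also stays open: 11 response genes outside the atrophy list differed by 0.335 (SE 0.346), with mutant 2 at 0.86. Mutants 1 and 3 lay at -0.215 and -0.139, close to the controls at -0.203 to -0.146. As a set these genes were not higher in mutants 1 and 3, although the members Klf9 and Sgk1 were. The set left out Per1 and all members of the atrophy list, and no bound was set for single libraries. It therefore cannot exclude such a signal in mutants 1 and 3. The genotype remains among the explanations, and these cannot be told apart with 3 libraries per group.

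The first principal component, with 41.3% of the variance, set controls 1 and 3 (-36.8 and -44.8) apart from control 2 (20.2) and the mutants (15.6 to 29.3). The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. At an adjusted p of 0.05 the real split gave 0 genes and the highest other 2; with a real count of 0, each of the 10 splits gives at least as many by construction, so this count says nothing about chance. At an unadjusted p below 0.05 the real split gave 1535 genes and the highest other 2334, for controls 1 and 3 with mutant 2. That was the only other split with as many, making 2 of 10 with the real one. Camera at the preset correlation passed 12 lists in the real split and up to 14 in the others; 5 of the 9 other splits gave as many, or 6 of 10 with the real one.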
